A study of Mus musculus with 4 samples.

How the data were processed

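Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed for Sp6 (also called epiprofin), a zinc-finger transcription factor of the SP/KLF family that is needed for normal tooth formation. Per the labels' protocols, dental epithelium and dental mesenchyme were separated from 30 molars of C57BL/6 mice on postnatal day 1, crosslinked and sonicated, and precipitated with a Sp6 antibody made in the submitters' laboratory. Each tissue has 1 Sp6 library and 1 input library (sonicated chromatin without antibody), 4 samples in all, with 1 library per group. Groups were taken from the sample titles. Per the labels' protocols the libraries were made by Active Motif and sequenced on an Illumina Genome Analyzer 2. The submitters' processing notes name the mouse genome build mm9 and the peak caller MACS 1.3.7.1. The aligner, the fragment length, the calling thresholds, any down-sampling or scaling of reads and the use of the inputs in calling are not given in the sources used here.

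For each of the 4 libraries the authors deposited a list of intervals, that is, regions with a local excess of sequenced fragments, and for each Sp6 library also a table that pairs intervals with genes. Each interval was called in 1 library, and nothing was pooled. The table gives an interval's signal as the authors' peak value, the fragment density in its highest bin, and as an average value over its bins, which have a median width of 32 bp per the file headers and values. No read totals are given, so the sequencing depth is unknown, and whether the libraries were scaled to one another is not stated. Peak values were therefore used to rank intervals within a library, and ratios between libraries are printed as deposited values only. Other deposited columns hold positions in bp, interval lengths, the number of CpG islands in an interval and the signed distance from the interval to a gene's start, per the file headers. The tables list genes from 10 kb upstream of the gene start, through the gene body, to past its end. They hold 2381 of the 3811 epithelium intervals and 7211 of the 11436 mesenchyme intervals, so peak values, CpG islands and genes are known for these alone, and they are called annotated intervals here. In 9 epithelium and 34 mesenchyme intervals the table names fewer genes than its own gene count. Coordinates are those of the deposited files, on mm9, counted from 1.

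Intervals of the 2 tissues were called shared when they overlapped by at least 1 bp. Sp6 intervals were compared with the intervals of both inputs together. Shares carry Wilson 95% intervals, which cover counting error only. The overlap was set beside 1000 circular shifts of the epithelium list within each chromosome. Intervals were described as near a promoter when they lay at most 5 kb from a listed gene start. Gene names were matched to the symbols and synonyms of a table of RefSeq genes (assembly GRCm38.p6), which was used for names, gene lengths and neighbouring genes only. Of the names in the deposited tables, 1999 of 2239 (89.3%) matched in epithelium and 4817 of 5391 (89.4%) in mesenchyme. Genes in both tissues were counted over 21631 protein-coding genes.

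Before the data were examined, 20 gene lists were fixed, holding 423 genes of which 421 were found among the protein-coding genes. The number of members with an interval was set beside 10000 random gene lists of the same size, drawn within 20 bins of gene length, and a list was called when its two-sided p, adjusted over the 40 tests by Benjamini-Hochberg, was under 0.05. Genes are not replicates, so a call describes these libraries, and the text gives the count beside the mean and the central 95% of the random lists. Within each tissue, the median peak value of shared intervals was compared with that of intervals in 1 tissue by a two-sided permutation test with 100000 resamples. With 1 library per group there is no replicate error and no test between tissues, so each test describes these libraries and lists. The list test was tested on simulated data over the same 21631 genes. A planted 6-fold rise in the odds of an interval was called in 50% of planted lists in epithelium and 72% in mesenchyme, and a 3-fold rise in 10% and 16%. Lists that were not planted were called in at most 0.667% of cases, though some of them share genes with planted lists. The simulation adjusted over the 20 lists of 1 tissue and used fewer random lists than the test, so these rates are approximate. A list that was not called may still differ.

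Genes are named by a rule fixed before the data were examined. It takes the 10 genes with the highest peak value in each tissue, the 10 genes of shared intervals with the highest mean rank, up to 4 members of each list per tissue, and 15 genes of prior interest (among them Sp6, Amelx, Ambn, Enam, Dspp, Msx1, Msx2, Pax9, Shh, Bmp4, Lef1, Rock1, Fst and Cdkn1a), which gave 100 genes. Unnamed transcripts were left out of the first parts, and ties were broken by symbol because the tables hold no p-value. Alternatives fixed in advance were a reciprocal overlap of 50%, the top 50% of each list by peak value, equal numbers of intervals, promoter windows of 1 kb and 10 kb, intervals touching an input interval left out, autosomes only, and random lists that were unmatched or matched on the span to neighbouring genes. Alternatives that rank intervals use annotated intervals, since peak values exist there only. A planned search for GC boxes and homeobox sites was not run, because no genome of the files' build was used here, and exon, intron and UTR positions were not analysed for the same reason. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.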

Results

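Sp6 occupancy was measured by ChIP-seq in dental epithelium, the tissue that forms enamel-secreting ameloblasts, and in dental mesenchyme, which forms dentin-secreting odontoblasts and pulp, from molars of C57BL/6 mice on postnatal day 1. Each tissue had 1 Sp6 library and 1 input library. The Sp6 library of the epithelium had 3811 intervals covering 2112 kb, with a median length of 542 bp. The Sp6 library of the mesenchyme had 11436 intervals covering 7579 kb, with a median length of 626 bp, which is 3 times as many. The inputs had 17 intervals in epithelium and 24 in mesenchyme. Peak values (the authors' fragment density in the highest bin) had a median of 27 in epithelium (interquartile range 21 to 38, highest 294) and 34 in mesenchyme (25 to 51, highest 584). There were no replicates, and read totals were not known.

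The first comparison asked whether Sp6 occupied the same places in the 2 tissues. Most epithelium intervals were also mesenchyme intervals. Of the 3811 epithelium intervals, 3350 (87.9%, Wilson 95% interval 86.8 to 88.9%) overlapped a mesenchyme interval, while 3340 of the 11436 mesenchyme intervals (29.2%, 28.4 to 30.0%) overlapped an epithelium interval. The strongest intervals lay at the same positions in both tissues. The highest mesenchyme peak value, 584, lay inside Gfra1, a GDNF receptor gene, 153.5 kb from its start (chr19:58375045–58375876), and the epithelium peak value there was 247. An interval upstream of Gas2l3 and past the end of Nr1h4 (chr10:88908812–88909492) had peak values of 415 in mesenchyme and 231 in epithelium.

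Other shared intervals at the top of both lists lay inside genes. In Ctnna2, which encodes alpha-N-catenin, the peak value was 394 in mesenchyme and 150 in epithelium. Smarcc1, a subunit of the BAF chromatin remodelling complex, had 374 and 132. Slc17a5, a lysosomal sialic acid transporter, had 374 and 130, and St8sia1, a ganglioside sialyltransferase, had 370 and 165. Pcsk2, a prohormone convertase, had 351 and 129, Adk (adenosine kinase) had 344 and 132, and Smyd3 had 333 and 166. Cdh2, which encodes N-cadherin, had 245 and 128, Mapkbp1 had 238 and 153, and Agpat3 had 219 and 137. Of the 10 genes with the highest epithelium peak values, 1 had no mesenchyme interval. This was Acacb, an acetyl-CoA carboxylase gene, with an epithelium peak value of 173 (chr5:114622838–114623254).

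In 1000 circular shifts of the epithelium list the overlap had a median of 21 intervals (range 8 to 39), and 0 shifts reached the observed 3350. Among 2079 pairs of annotated shared intervals, the median distance between peak centres was 32 bp and 95.7% lay within 100 bp. The deposited peak value was higher in mesenchyme in 1953 pairs, higher in epithelium in 112 and equal in 14. The median log2 ratio of epithelium to mesenchyme was −0.97 (interquartile range −1.35 to −0.58). Across pairs, which are not independent replicates, log2 peak values had a Pearson correlation of 0.717 and a Spearman correlation of 0.659. Because scaling between libraries is not stated, the ratio describes the deposited values and does not measure a difference in binding. When the mesenchyme list was reduced to its 2381 highest annotated intervals, as many as epithelium had, 59.9% of them and 60.2% of the epithelium intervals were shared.

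**Figure D1:**
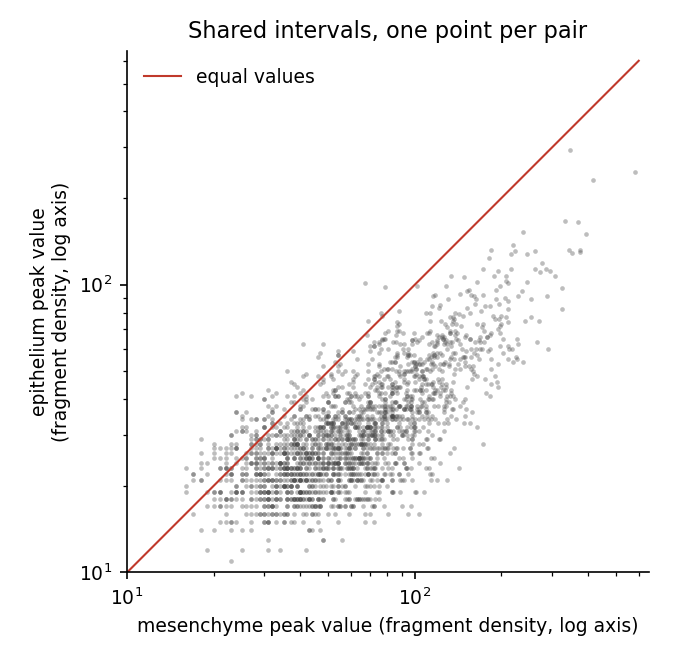
Peak value (fragment density, log axes) of each of the 2079 shared annotated intervals in mesenchyme (x) and epithelium (y), 1 point per pair, with a line of equal values. Most points (1953) lie below the line, where the mesenchyme value is higher.

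Shared intervals had higher peak values than intervals of 1 tissue. In epithelium the median was 29 in 2080 shared intervals and 19 in the 301 others. In mesenchyme it was 58 in 2073 shared intervals and 30 in 5138 others (permutation test, two-sided, p = 1e-05 in each tissue, the smallest that 100000 resamples can give). The share of mesenchyme intervals with an epithelium counterpart was 3.19% (2.13 to 4.73%) in the lowest of 10 equal groups by peak value and 89.2% (86.7 to 91.2%, 643 of 721) in the highest. In epithelium the share was 58.2% (51.8 to 64.2%) in the lowest group, 238 of 238 in the group next to the highest and 96.6% (93.5 to 98.3%, 230 of 238) in the highest.

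**Figure D2:**
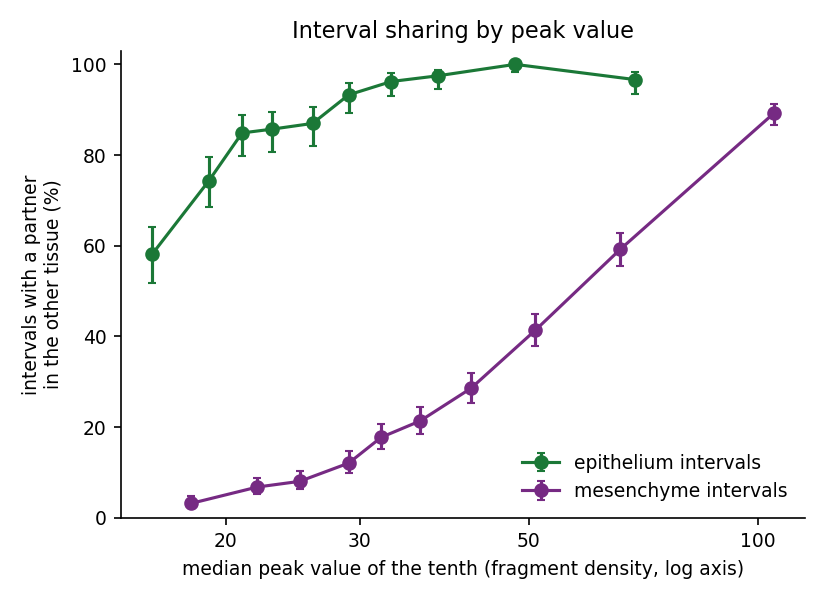
Share of intervals with a counterpart in the other tissue (y, %) in 10 equal groups by peak value (x, median fragment density of the group, log axis), for epithelium and mesenchyme; bars are Wilson 95% intervals, which cover counting error. In mesenchyme the share goes from 3.19% in the lowest group to 89.2% in the highest.

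Few Sp6 intervals lay on input intervals. The inputs had only 17 and 24 intervals, so this share could only be small, and it does not measure background. How the inputs were called is not stated. In epithelium 13 Sp6 intervals touched an interval of either input (0.341%, 0.199 to 0.583%), 9 of them in the input of the same tissue. In mesenchyme 14 did (0.122%, 0.0729 to 0.205%), all 14 in the input of the same tissue. Among the 13 in epithelium was the strongest annotated interval of that list (chr17:39979757–39985863), with a peak value of 294 in epithelium and 347 in mesenchyme. It is listed for LOC627695 and for the microRNA Mirn715, downstream of it at 3.784 kb from its start. Both inputs had an interval over most of it, of 5953 bp in epithelium and 5985 bp in mesenchyme. Of the genes named here, the intervals of Lrp5, a WNT co-receptor, and 1 weak mesenchyme interval shared by Dlx1 and Dlx2 (chr2:71379449–71382440, peak value 20) also touched an input interval, in each case of the mesenchyme input. All 17 epithelium input intervals and all 24 mesenchyme input intervals overlapped a Sp6 interval of the same tissue by at least 1 bp.

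The next comparison described where the intervals lay relative to genes. Most annotated intervals were inside gene bodies, 77.1% (75.4 to 78.8%) in epithelium and 75.95% (74.95 to 76.93%) in mesenchyme. A further 14.3% and 15.8% were upstream of genes and 8.61% and 8.27% downstream only. Annotated intervals within 5 kb of a gene start made up 20.6% (19.0 to 22.3%, 491 of 2381) in epithelium and 23.6% (22.6 to 24.6%, 1699 of 7211) in mesenchyme. Annotated intervals are those with a listed gene, so these shares are higher than shares of all intervals. Of all intervals, 12.9% (491 of 3811) and 14.9% (1699 of 11436) lay within 5 kb of a listed start. No genomic background was set beside these shares. Intervals on CpG islands, CpG-rich stretches found at the promoters of many genes, numbered 100 in epithelium (4.2%, 3.47 to 5.08%) and 609 in mesenchyme (8.45%, 7.83 to 9.11%). Of these, 91 in epithelium and 569 in mesenchyme lay within 5 kb of a listed start. In mesenchyme the CpG island share was 3.86% (3.11 to 4.78%) in shared intervals and 10.3% (9.49 to 11.2%) in intervals of mesenchyme alone. In epithelium it was likewise 3.27% (2.59 to 4.12%) in shared intervals and 10.6% (7.63 to 14.6%) in intervals of epithelium alone. With a window of 1 kb the promoter shares of annotated intervals were 5.42% and 8.90%, and with 10 kb they were 34.3% and 36.1%.

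At the level of genes, 1783 protein-coding genes had an interval in both tissues, 92.4% of the 1929 genes of epithelium. Of annotated epithelium intervals 87.4% overlapped a mesenchyme interval, so the gene overlap and the folds below largely restate the interval overlap. Independent lists of these sizes would share 412 genes, so the overlap was 4.32-fold. Within 20 bins of gene length they would share 691, and the overlap was 2.58-fold. The fold within length bins was 3.66 at equal numbers of intervals, 3.53 in the top 50% of intervals, 11.9 within 5 kb of a gene start and 24.3 within 1 kb (7.61, 7.81, 12.6 and 25.4 without length bins). A further 2840 genes had an interval in mesenchyme only and 146 in epithelium only. These counts follow the list sizes. At equal numbers of intervals 1258 genes were in both (65.2% of those of epithelium), 595 in mesenchyme only and 671 in epithelium only. Long genes were over-represented, with a median length of 64.9 kb for genes of epithelium and 46.5 kb for genes of mesenchyme, against 17.3 kb for all protein-coding genes. All list tests below were matched on gene length for this reason.

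Sp6 intervals were listed for many of the enamel genes in both tissues. Of the 22 genes for enamel matrix and maturation, 12 had an interval in epithelium, where random lists matched on gene length had 2.00 on average (0 to 5 in the central 95% of lists). In mesenchyme 13 had one, against 4.91 (2 to 9). Both counts were called above the random lists after adjustment over all lists and tissues. Both tissues shared Amelx, Ambn, Enam, Amtn and Odam, which encode matrix and ameloblast-associated proteins. They also shared Mmp20, the enamel matrix protease, and Car2, Relt, Slc26a3, Stim1 and Wdr72. Klk4, the late-stage protease, had an interval in epithelium only, downstream of the gene at 10658 bp from its start. Alpl and Slc26a4 had one in mesenchyme only, downstream at 60782 and 48498 bp from their starts. Some shared genes also had distant intervals, such as Stim1, with epithelium intervals 113614 and 145518 bp from its start. The calls held under every alternative run for this list, none of which was limited to intervals near gene starts.

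Ambn, Enam, Amtn and Odam lie in one cluster on chromosome 5. From position 88317436 to 88936479, a span of 619 kb, epithelium had 8 intervals and mesenchyme had 10. The span runs from the first to the last mesenchyme interval of these genes, so no density was compared. The interval 0.172 kb upstream of the Ambn start had a peak value of 42 in epithelium (chr5:88884516–88885300) and 93 in mesenchyme (chr5:88883891–88885319). Enam had peak values of 33 and 51 directly upstream of its start. At Odam, just inside the gene, they were 37 and 109, and downstream of Amtn they were 36 and 78. Mmp20 had 29 in epithelium and 42 in mesenchyme directly upstream of its start, and 45 and 38 inside the gene. Amelx, on the X chromosome, had 4 intervals in epithelium (highest 28) and 5 in mesenchyme (highest 35, chrX:165622151–165625654). All of these are also listed for Arhgap6, the gene in which Amelx is nested.

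**Figure D3:**
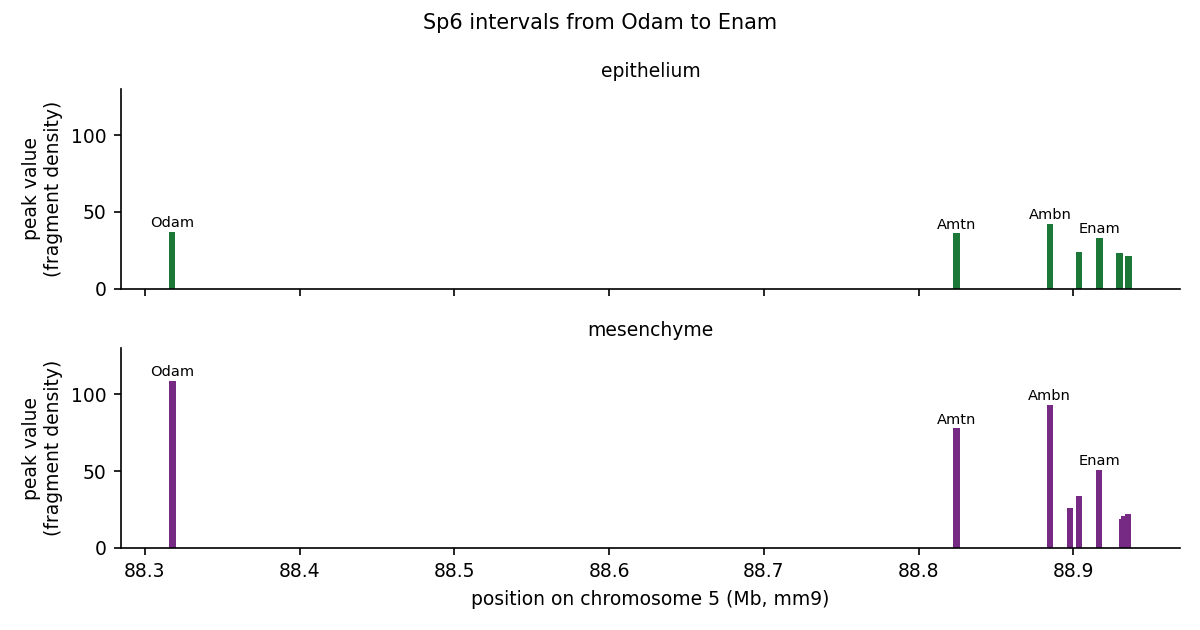
Sp6 intervals across the enamel gene cluster on chromosome 5 (x, position in Mb, mm9), 1 bar per annotated interval with its peak value as height (y, fragment density), in epithelium (top) and mesenchyme (bottom). The tallest bars are at Ambn (42) in epithelium and at Odam (109) in mesenchyme.

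Genes of dentin and its matrix were also occupied in both tissues. Of 16 odontoblast and dentin genes, 6 had an interval in epithelium (random mean 1.81, central 95% 0 to 4) and 12 in mesenchyme (3.89, 1 to 7), and both were called. Dspp, the major non-collagenous dentin protein gene, had an interval directly upstream of its start, with peak values of 24 in epithelium (chr5:104599137–104599662) and 59 in mesenchyme (chr5:104598781–104600155). Dmp1 had shared peak values of 18 and 43 past the gene, about 14.5 kb from its start, and Col1a2 42 and 117 at about 1.9 kb. Runx2, an osteogenic transcription factor, had 27 and 33 inside the gene, about 146.6 kb from its start. Mesenchyme alone had higher values at Dmp1 (79) and Runx2 (46). Of these genes 6 are held by another list. Without them 2 of 10 were occupied in epithelium, where the call was lost, and 6 of 10 in mesenchyme, where it held. Neither call held among the top 50% of intervals by peak value, where 1 and 6 of the 16 genes were occupied, and the mesenchyme call was also lost at equal interval numbers.

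The 9 DLX and MSX homeobox genes, which pattern jaws and teeth, had intervals at 4 members in epithelium (Dlx2, Dlx3, Dlx5 and Msx2; random mean 0.305, central 95% 0 to 2). In mesenchyme 7 had one, with Dlx1, Dlx4 and Msx1 in addition (1.00, 0 to 3). Both were called. At Msx2 the strongest interval lay over the gene start, with peak values of 37 in epithelium (chr13:53567981–53568726) and 136 in mesenchyme (chr13:53565862–53569449). Dlx2 had 18 and 58 about 1.5 kb upstream of its start, and Dlx3 23 and 61 past the gene, about 18.3 kb from its start. Dlx5 had 33 and 50 at 7.07 kb upstream. The highest mesenchyme value at Dlx5 was 60, downstream of the gene, with no epithelium counterpart. Msx1 had 1 weak mesenchyme interval, with a peak value of 19. The epithelium call was lost when random genes were matched on the span to their neighbours and in the top 50% of intervals. Of the 9 genes, 7 are held by another list.

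Among 20 transcription factors of dental epithelium, 8 had an interval in epithelium (random mean 1.95, central 95% 0 to 5) and 12 in mesenchyme (4.57, 1 to 8), and both were called. Sp6 itself had 2 intervals in epithelium and 7 in mesenchyme. The strongest lay about 2.1 kb upstream of its start, with peak values of 56 in epithelium (chr11:96872454–96873402) and 149 in mesenchyme (chr11:96871740–96873714). Satb1, a chromatin organiser, had peak values of 60 and 168 inside the gene, 66.1 kb from its start. Sox21 had 21 and 76 at 2.44 kb upstream. Lef1, a WNT effector, had 19 and 24 at about 103.8 kb, with a mesenchyme value of 25 elsewhere in the gene. Without the 5 genes held by other lists, 3 of 15 in epithelium and 7 of 15 in mesenchyme were occupied and both calls were lost. In the top 50% of intervals the epithelium call was also lost.

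**Figure D4:**
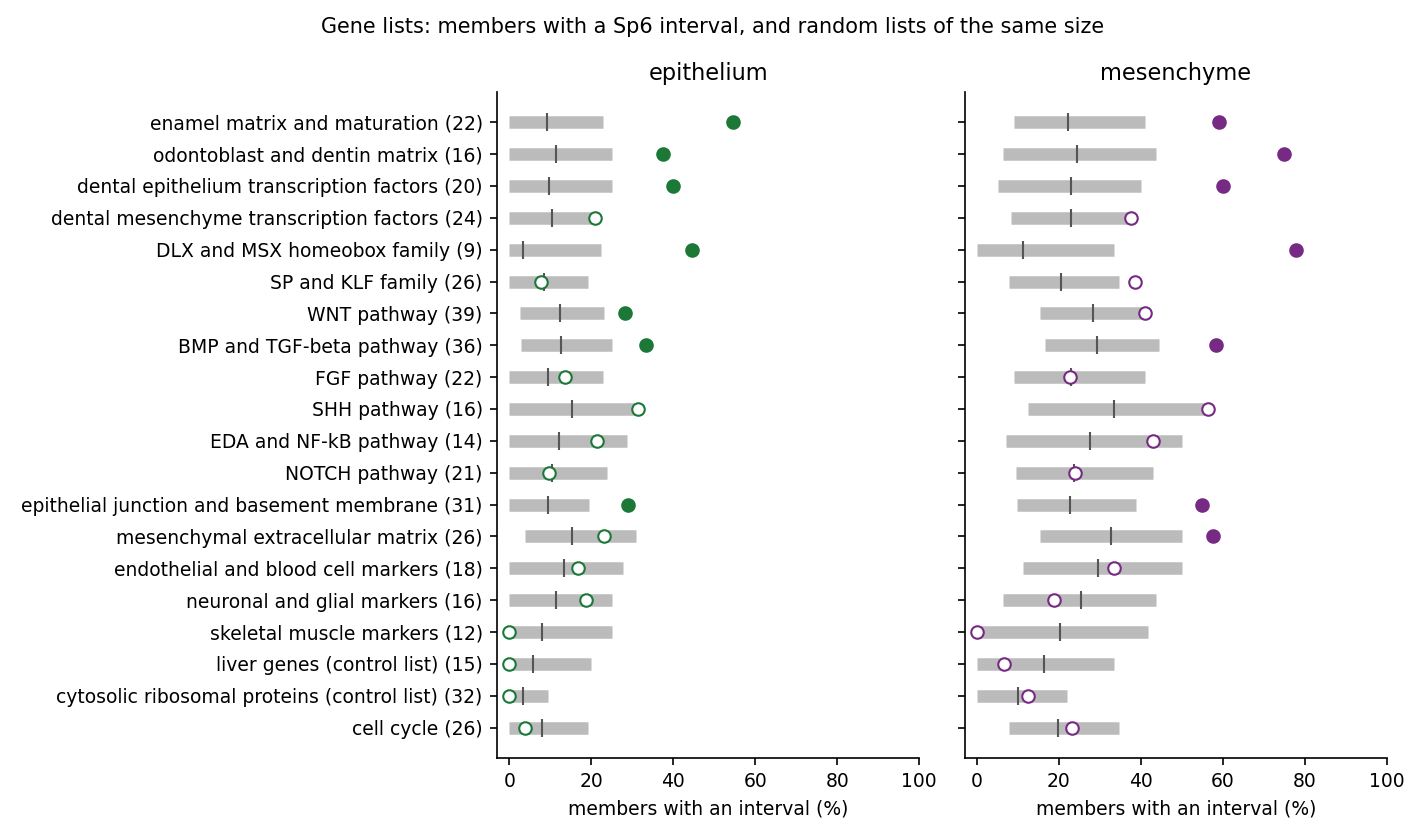
Share of each fixed list's members with a Sp6 interval (x, %; list size in brackets) in epithelium (left) and mesenchyme (right). Filled circles passed the adjusted p of 0.05 and open circles did not; grey bars span the central 95% of 10000 random lists matched on gene length, with their mean as a tick. In each tissue 7 of 20 lists passed, all above their random lists.

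The BMP and TGF-beta pathway, which signals between the 2 dental tissues, had intervals at 12 of 36 genes in epithelium (random mean 4.56, central 95% 1 to 9) and at 21 in mesenchyme (10.5, 6 to 16), and both were called. Bmp4 had an interval 0.382 kb upstream of its start, with peak values of 64 in epithelium (chr14:47010368–47011001) and 128 in mesenchyme (chr14:47010118–47011079). Smad2 had 53 and 101 past the gene, 72.2 kb from its start. Smad6 had 37 and 96 at 7.82 kb and Tgfbr2 37 and 84 at 69.3 kb, both inside the gene. The WNT pathway was called in epithelium, with 11 of 39 genes (random mean 4.83, central 95% 1 to 9), and not in mesenchyme, with 16 (11.1, 6 to 16). The difference between the tissues was not tested. Lgr6, an R-spondin receptor, had 70 and 195 inside the gene, 93.3 kb from its start. Apc had 35 and 87 at 88.3 kb and Ctnnb1, which encodes beta-catenin, 24 and 66 at about 14.2 kb, both inside the gene. In epithelium the BMP call was lost in the top 50% of intervals. The WNT call was lost there, with genes of other lists left out, with matching on the span to neighbours and without intervals on input. The last leaves out Lrp5, whose 1 epithelium interval lies downstream of the gene on an interval of the mesenchyme input. With unmatched random lists WNT was also called in mesenchyme.

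Epithelial junction and basement membrane genes had intervals at 9 of 31 members in epithelium (random mean 2.92, central 95% 0 to 6) and 17 in mesenchyme (7.01, 3 to 12), and both were called. Nectin1, an adhesion receptor gene, had 84 and 183 at 7.54 kb upstream of its start. Inside the genes, Pkp1 (plakophilin) had 38 and 40 at about 18.0 kb, Cldn1 20 and 72 at about 11.8 kb and Lama3 33 and 56 at 137.5 kb. Mesenchymal extracellular matrix genes were called in mesenchyme, with 15 of 26 (8.51, 4 to 13), and not in epithelium, with 6 (3.97, 1 to 8). The difference was not tested. Cdh2, Col1a2, Col5a2 and Itgav had intervals in both tissues, and Dcn (decorin) had one in mesenchyme only, with a peak value of 73. The junction call in epithelium was lost in the top 50% of intervals. The matrix call was lost at equal interval numbers and with genes of other lists left out.

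The other 12 lists were not called in either tissue. Dental mesenchyme transcription factors had intervals at 5 of 24 genes in epithelium and 9 in mesenchyme. Among them, Gli3 had peak values of 55 and 137 inside the gene, about 247 kb from its start. The SP and KLF family had 2 of 26 (Sp6 and Sp9) and 10. The SHH pathway had 5 of 16 and 9, the latter called with unmatched random lists. Further counts were EDA and NF-kB 3 of 14 and 6, FGF 3 of 22 and 5, and NOTCH 2 of 21 and 5. Cell cycle genes had 1 of 26 (Rb1) and 6. Markers of other cell types, also not called, had 3 of 18 and 6 for endothelial and blood cells and 3 of 16 and 3 for neurons and glia. Skeletal muscle markers had 0 of 12 in each tissue. The control lists had 0 of 15 and 1 (Alb) for liver genes and 0 of 32 and 4 (Rpl3, Rpl37, Rps2 and Rps18) for ribosomal proteins.

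Of other genes of prior interest, Shh had 1 mesenchyme interval at its start with a peak value of 18, and Cdkn1a, a cell cycle inhibitor, had 3 mesenchyme intervals with a highest value of 37. Neither had an interval in epithelium. Pax9, Rock1 and Fst had no listed interval in either tissue. An absent interval means that none was called at this unknown depth, not that the site was unoccupied. Over the 10 lists with at least 5 shared intervals, 0 had a median ratio of epithelium to mesenchyme peak value outside random shared intervals of similar strength after adjustment. Before adjustment 2 lists did, DLX and MSX genes (median log2 ratio −1.55) and dental epithelium transcription factors (−1.45), both lower in epithelium than random shared intervals.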

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

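The tests of binding near mesenchymal genes, of epithelial cells in the mesenchyme sample and of highly transcribed genes were chosen after the pattern they address had been seen. A signal outside the gene-based comparisons drew attention in both tissues. In epithelium 1430 Sp6 intervals, and in mesenchyme 4225, lie outside the gene tables, against 17 and 24 intervals in the whole input lists. How the inputs were called is not stated. These intervals without a listed gene were shared between the tissues about as often as annotated ones, at 88.8% (87.1 to 90.3%) against 87.4% (86.0 to 88.6%) in epithelium and 30.0% (28.6 to 31.4%) against 28.7% (27.7 to 29.8%) in mesenchyme.

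Mesenchyme had 3 times as many intervals as epithelium. Weaker enrichment or fewer usable fragments in the epithelium library is a candidate explanation. The share of mesenchyme intervals with an epithelium counterpart went from 3.19% in the lowest of 10 equal groups by peak value to 89.2% (86.7 to 91.2%) in the highest. Weaker sites bound in mesenchyme alone would give such a rise too. The bound set in advance for weaker enrichment or fewer fragments was 90% in the highest group, so the test did not decide. Binding near mesenchymal genes that is absent from epithelium is a candidate explanation for part of the excess of intervals. Intervals without an epithelium counterpart made up 57 of 74 at the mesenchymal lists and 60 of 99 at the epithelial lists, a difference of 16.4 percentage points (95% interval 2.35 to 29.2), with an odds ratio of 2.57 (1.12 to 5.90) within 5 equal groups of peak value. Set against all other annotated mesenchyme intervals, of which 71.2% had no counterpart, the mesenchymal lists did not stand apart (77.0%, 66.3 to 85.1%, odds ratio 1.48, 0.765 to 2.86). The epithelial lists were shared more often than the rest (60.6% without a counterpart, 50.8 to 69.7%, against 71.4%, odds ratio 0.574, 0.347 to 0.95045). The difference therefore does not decide for this explanation. Tissue and library are confounded with 1 library each, and intervals of one gene are not independent.

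Intervals at enamel genes in the mesenchyme library may come from epithelial cells in that sample, from chromatin of highly transcribed genes captured whatever the antibody, or from Sp6 binding in mesenchyme itself, which no test here addresses. With epithelial cells as the source, enamel genes would have a higher epithelium to mesenchyme ratio than other shared intervals. Their median log2 ratio was −0.81 over 19 shared intervals, inside the −1.11 to −0.60 of random shared intervals of similar strength. Cytosolic ribosomal protein genes, which are highly transcribed in all cells, had an interval at 4 of 32 genes in mesenchyme, inside the 0 to 7 of random lists, and at 0 of 32 in epithelium. No other set of highly transcribed genes was tested. In mesenchyme, runs of weak intervals lay along Amelx (chrX:165616256–165625654, peak values 28 to 35) and Col1a1 (chr11:94795542–94817318, 14 to 33). How many genes hold such runs was not tested. None of these values decides between the explanations.

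CpG island intervals were mostly in the mesenchyme list (609 against 100). In both tissues they were more frequent among intervals of that tissue alone (10.3% in mesenchyme and 10.6% in epithelium) than among shared ones (3.86% and 3.27%). For weak promoter background called only in the library with more intervals, the prediction set in advance held. In mesenchyme 20.2% of intervals lay on a CpG island in the lowest of 4 equal groups by peak value and 2.66% in the highest, a difference of 17.6 percentage points. That explanation does not cover the excess among intervals of epithelium alone. In epithelium the CpG island share was 10.5% in the lowest of 10 equal groups by peak value and 1.68% in the highest. Weak binding would give the same values as background, so the test cannot separate them. Lower peak values may be the whole reason why CpG island intervals of mesenchyme lack an epithelium counterpart. Counterparts were found for 13.1% of CpG island intervals and 30.2% of the others (odds ratio 0.350), but within 10 equal groups of peak value the odds ratio was 0.952 (0.712 to 1.27). So among mesenchyme intervals of similar peak value no clear deficit of counterparts at CpG islands was seen, and the range leaves room for a small one. Whether binding at CpG islands differs between the tissues cannot be told from 1 library each.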

How the results depend on the processing

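Alternatives that filter one list only, that compare the top mesenchyme intervals with every epithelium interval, that use annotated intervals only, that use the input of the same tissue only, that leave out genes of other lists, that test the lists without input intervals or that bin genes by length for the expected overlap were chosen after the data were seen. The overlap of the 2 lists moved with the rule and the list size. The epithelium share was 82.7% at a reciprocal overlap of 50%, 90.4% in the top 50% of each list, 60.2% at equal numbers and 96.5% for the top 50% of epithelium intervals against every mesenchyme interval. The mesenchyme share was 27.6% at 50% overlap, 59.9% at equal numbers, 48.0% for the top 50% against every epithelium interval and 59.9% for as many top intervals as epithelium had. The promoter share of annotated intervals was 17.3% in epithelium and 17.9% in mesenchyme in the top 50%. It was 5.42% and 8.90% at 1 kb, and 34.3% and 36.1% at 10 kb. Genes in both tissues numbered 963 in the top 50%, 1258 at equal numbers, 80 within 1 kb and 372 within 5 kb of the start. Fewer intervals by construction set these counts. Of the 7 lists called in epithelium, 1 was called in the top 50% and 3 with genes of other lists left out, and in mesenchyme 4 were called with such genes left out. The cause was not tested. Odontoblast genes in epithelium fell to 0.973 times their random lists in the top 50%. Over all lists and settings 219 results kept their side of the threshold, 16 lost the call, 2 gained it and 1 was counted as reversed. No list was called below its random lists in any setting, so the reversed result was not an opposite call. Leaving out intervals on input or on sex chromosomes kept each overlap within its counting interval. The input filter removed only 13 epithelium and 14 mesenchyme intervals, so it could hardly move the overlap. The higher peak value of shared intervals kept its call in each setting run. Of 168 highest peak values at named genes, 164 were the same without input intervals and 4 had no interval left. Within 5 kb of the start 50 were the same, 22 were lower and 96 had no interval left. The DLX and MSX list could not be tested without genes of other lists, since fewer than 5 were left. The motif search was not run, no replicate could be left out and no other splits exist with 1 library per group. No paired analysis was possible because each group has 1 library and the results come from no test between groups. Unknown depth limits every absent interval.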

Other observations

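The tests of interval length were chosen after the data were seen, and so were the genes singled out here. Leaving out intervals on input, 51 annotated mesenchyme intervals exceeded 2 kb, and none did in epithelium. The longest, 9745 bp (chr19:5794687–5804431), is listed for the long non-coding RNA gene Neat1. Another long interval, listed for Frmd8 and Neat1, lay at chr19:5843080–5847401, and which gene the longest one covers was not checked. The longest was followed by intervals of 5330 bp at Id3 and 4828 bp at Id1, which encode BMP-induced inhibitors of bHLH factors. Next were 4622 bp at an interval listed for Scrn2, Lrrc46 and Sp6 (chr11:96887169–96891790) and 4501 bp at Msx2 (chr13:53561269–53565769). Others among the 20 longest lay at Bambi, a BMP and TGF-beta pseudoreceptor (4012 bp, peak value 141), Amelx (3504 bp), the gap junction gene Gja1 (3391 bp), Jund (3002 bp) and Dlx5 (2638 bp). The 20 also include intervals at Chd2, Brd2, Ube2n, Ddx5, Marcks and Zfp36l1, and which kinds of gene they hold was not tested. Their median peak value was 35, against 34 in all annotated mesenchyme intervals, and 6 of them touched an epithelium interval. The 20 longest epithelium intervals were at most 1394 bp, and all 20 were shared.

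Interval length was also set beside 10000 random sets of intervals of similar peak value, over 28 tests with Benjamini-Hochberg adjustment. Intervals at DLX and MSX genes in mesenchyme had a median length of 1351.5 bp over 22 intervals, against 630.5 bp in random sets (central 95% 563 to 696 bp). Dental epithelium transcription factors had 821.5 bp against 635.5 bp (589 to 683 bp), and the SP and KLF family 790 bp against 612 bp (534 to 699 bp). Odontoblast genes had 719 bp against 619 bp (554 to 683 bp) and dental mesenchyme transcription factors 738.5 bp against 635 bp (573 to 698 bp). These 5 of 18 mesenchyme lists passed. Another 4 lay above their central 95% before adjustment, namely the WNT, BMP and TGF-beta and extracellular matrix lists and the ribosomal control list. The control list had 837 bp against 593 bp (452 to 824 bp) over 5 intervals, a larger ratio than 4 of the 5 lists that passed. The enamel list did not pass, at 675 bp against 637 bp (582 to 691 bp). In epithelium 0 of 10 lists passed, and 2 lay above their central 95% before adjustment. Several intervals belong to one gene, and 7 of the 9 DLX and MSX genes are in another list, so the tests are not independent.

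Some genes held many intervals. In mesenchyme Sema5a had 17, of which 5 were shared, and Dnm3 had 12, of which 0 were shared. Ctnna2 had 16 with 1 shared. Satb1, 97.1 kb long, had 10, where genes of similar length had 0.667 on average. In epithelium Tanc1 had 8, of which 6 were shared, and Amelx had 4, where genes of similar length had 0.0564.

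In the highest of 10 equal groups of epithelium intervals by peak value, 8 had no mesenchyme counterpart, and 3 of those touched an input interval. Their median length was 410 bp, against 647 bp for shared intervals of that group, but 2 of the 3 on input were longer (1986 and 1649 bp). Besides Acacb (417 bp, peak value 173), the 8 include an interval of 282 bp upstream of Dtwd1 (chr2:125973541–125973822, peak value 100) and one of 403 bp near Fgf21 (chr7:52878891–52879293, peak value 71). The mesenchyme interval of highest peak value without a counterpart lay in Tmem117 (chr15:94775292–94775968, peak value 132).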
